A study of Homo sapiens with 4 samples.

How the data were processed

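RNA sequencing was done on 4 human libraries, 1 per group, labelled as breast cancer cells of the MCF-7 line, of the ZR-75 line, and of each line overexpressing eIF4E, the protein that binds the mRNA cap and starts translation. Total RNA was extracted with Trizol and libraries were made with a stranded mRNA kit, per the labels' protocols. Per the labels, the lines were grown in different media (DMEM for MCF-7, a medium free of phenol red for ZR-75, both with serum), so cell line and medium cannot be separated. Each library's group was taken from its label.

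The authors deposited 1 table of 60725 gene rows that holds, per library, a TPM column and a column of normalised read counts. STAR 2.5.2, RSEM 1.2.31 and the GRCh38 genome are named in the submitters' processing notes. The annotation release, the RSEM settings, the strand used for counting and the normalisation are not given in the sources used here. Genes are named by the symbols, identifiers and coordinates in the table.

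The deposited normalised read counts (treated here as a signal, since they are neither raw counts nor CPM) were found to be estimated reads multiplied by 1 constant per column. The constants were 1.52 for the MCF-7 control, 1.32 for the ZR-75 control, 1.17 for the library labelled MCF-7 overexpression and 1.17 for that labelled ZR-75 overexpression. Divided by its constant, every nonzero value of both controls was a multiple of 0.01 read (within 0.01 of that step), and between 84.1% and 85.1% of nonzero values were whole reads (within 0.01 read). In both libraries labelled overexpression the normalised counts of 4 genes, EIF4E, ESR1, FOXM1 and RUNX2, were not on that grid, and for ESR1 neither was the TPM. The TPM columns, per the file headers, were found to be TPM divided by a round constant per column (0.7, 0.6, 0.8 and 0.7 in the order above), and were multiplied back. The TPM of all other genes leave a remainder under the fixed total of a TPM column for these 4 genes, which was compared with their deposited TPM. The 4 genes were left out of library totals, scaling, tests and gene lists, and their deposited values are given with that remainder.

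The authors' fold columns, deposited as linear ratios, equalled the plain ratio of the TPM or normalised count columns in every gene with a value (0 differed by more than the rounding error of the computation). The deposited posterior probability of differential expression (PPDE), a score between 0 and 1 given with a direction over both lines, was quoted and set against the deposited TPM ratios. It covers 28291 rows; the program behind it is not given in the sources used here.

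Estimated reads, without the 4 genes, totalled 20119179 in the MCF-7 control, 19494804 in the ZR-75 control, 19197566 in the library labelled MCF-7 overexpression and 19260062 in that labelled ZR-75 overexpression. A count of 0 allows up to 3 reads, or 0.149 to 0.156 CPM before scaling. Counts were scaled with an own implementation of the trimmed mean of M values (TMM; 30% of ratios and 5% of levels trimmed at each end), which gave factors of 0.918, 0.938, 1.07 and 1.08 in the order above, and expressed as CPM. All-gene medians of the log2 change were 0.03 under the MCF-7 labels and 0.00 under the ZR-75 labels with TMM, and 0.24 and 0.20 with library totals alone. Changes are therefore relative to that scaling.

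With 1 library per group, no test or p-value was possible within a line. Changes within a line are log2((CPM + 0.5) / (CPM + 0.5)), which understates the change of low genes. A gene was counted as higher or lower by a rule of size: at least 2-fold, with at least 1 CPM in at least 1 of both libraries. Folds of single genes are ratios of CPM without the pseudocount, with a 95% exact binomial interval, and against a count of 0 a lower bound at 3 reads. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

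The response common to both lines was tested with limma 3.58.1 (R 4.3.3; trend and moderated variance, two-sided) on log2(CPM + 1) of 15345 genes with at least 1 CPM in at least 2 libraries, with cell line and overexpression label as terms. The lines are the only replication, so the fit has 1 residual degree of freedom (5.05 prior degrees of freedom), and p-values measure how alike the lines' changes are, not the spread between independent cultures. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The same model gave the difference between lines, and a fit with the ZR-75 labels exchanged counted genes that move in opposite directions. That fit takes the shared change into its residual, so a count of 0 from it is not read as a result. The line term likewise takes a difference seen under only 1 state label into its residual. A count model had been planned; since the values are not raw counts, limma was used in its place, and DESeq2 and edgeR were not used.

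Before the data were examined, 23 gene lists were fixed: estrogen receptor targets, FOXM1 and G2/M genes, G1/S and DNA replication genes, translation initiation factors, cytosolic ribosomal proteins, eIF4E-sensitive mRNAs, unfolded protein response, integrated stress response (ATF4 targets), interferon response, cholesterol synthesis, hypoxia and glycolysis, p53 targets, nuclear oxidative phosphorylation genes, growth factor receptors and ligands, immediate early genes, NF-kB and cytokine genes, luminal, basal, mesenchymal and fibroblast, and immune cell markers, mitochondrially encoded mRNAs, replication-dependent histones, and genes of tamoxifen metabolism and drug transport. Some members stand under an older and a newer symbol, so not every listed symbol has a row; for the histones 20 of 34 did. Per line, a list's median was set against 10000 random lists of its size matched on mean expression in 20 bins. The lists were tested on the shared fit with camera (limma, preset correlation 0.01), adjusted over the 23 lists, and again with an estimated correlation and with fry.

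The genes named were chosen by a rule fixed before the data were examined: EIF4E, ESR1 and FOXM1; per line the 8 largest increases and 8 largest decreases with at least 10 CPM in at least 1 library; for the shared response the 10 smallest p in each direction; up to 4 members of each list with the largest mean change; and for the line difference the 5 highest and 5 lowest (at least 10 CPM in a library) with ESR1, PGR, ERBB2, GATA3, FOXA1, CDH1 and TP53. Outside that rule, RUNX2 was named for its place among the 4 genes above, and MTAP, CD44, NEFL, NEFM, INA, LIN28B, PAX2 and other markers of cell lines were chosen after part of the data had been seen.

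The procedures were tested on simulated counts made from the real means. For the shared response (15071 genes), 92 of 100 genes changed 2-fold and 98 of 100 changed 4-fold were recovered, and 6 unchanged genes were called. Only these genes were changed, equally in both lines and without scaling factors. The simulation therefore does not measure error where most genes differ, as in the real data. The exchanged labels (15053 genes, simulated without a shared change, so not a measure of power in the real data) gave 91, 99 and 10 in the same order. The line difference (14983 genes) gave 84, 98 and 10. It was simulated as equal under both state labels, so it does not measure power for a difference between the controls alone. Of 22 unchanged lists 0 were called, and the 1 changed list was. The rule of size (14685 genes) found 93 of 100 genes changed 2.8-fold and 100 of 100 changed 8-fold, with 13 of 14467 unchanged genes; 6 of 100 unchanged lists lay outside the central 95% of random lists. TMM returned a factor of -0.71 on the log2 scale for -0.74 put in. Other scalings, pseudocounts, filters, fold thresholds and tests were run as alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.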

Results

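The libraries measure polyadenylated RNA and are labelled as MCF-7 and ZR-75, estrogen receptor positive breast cancer lines, and as each line overexpressing eIF4E, with 1 library in each of the 4 groups. The line names are those of the labels throughout. The estimated reads lay between 19197566 and 20119179 per library, and between 22006 and 22611 genes had a value above 0. The 10 most abundant genes took 7.37% of reads in the MCF-7 control and 7.48% in the ZR-75 control, against 5.45% and 5.44% in the libraries labelled MCF-7 and ZR-75 overexpression. No group has replicates, so values within a line carry counting error only, and the comparison over both lines rests on how alike the lines' changes are.

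EIF4E is the gene the labels say was overexpressed, but its deposited values cannot check those labels, because they exceed what the TPM total allows. They correspond to 68.9 CPM in the MCF-7 control and 69.2 CPM in the ZR-75 control, against 8602 CPM in the library labelled MCF-7 overexpression and 10027 CPM in that labelled ZR-75 overexpression, log2 changes of 6.95 and 7.17. EIF4E (ENSG00000151247.12) lies on chromosome 4, from 98871684 to 98930637 on the minus strand of GRCh38. FOXM1, a transcription factor of the G2/M genes (ENSG00000111206.12, chromosome 12, 2857681 to 2877155), stood at 238 and 217 CPM in the controls and at 2196 and 1925 CPM in the libraries labelled overexpression, log2 changes of 3.20 and 3.15. ESR1, which encodes estrogen receptor alpha (ENSG00000091831.21, chromosome 6, 151656691 to 152129619), went from 544 to 685 CPM under the MCF-7 labels and from 468 to 795 CPM under the ZR-75 labels, log2 changes of 0.33 and 0.76. RUNX2, a transcription factor of bone formation, had log2 changes of 0.21 and -0.08. In the authors' deposited table, EIF4E is listed as up with a PPDE of 1.000, FOXM1 as up with 0.997, and ESR1 and RUNX2 as down with 1. The direction of ESR1 goes against its deposited values. Among other genes with at least 1000 mean estimated reads, 2503 had log2 TPM ratios of at least 0.5 in size and of 1 sign in both lines. Of these 0 were listed against their sign. The log2 TPM ratios of ESR1, 0.15 and 0.14, are below that size, so this count does not cover genes with changes as small. Among genes with at least 1000 mean estimated reads, 52 had TPM ratios of 8 or more in both lines, and 0 of them had a PPDE as low as that of FOXM1 or EIF4E. Another 268 had TPM ratios within 1.1-fold in both lines, and 34 of them had a PPDE printed as 1.

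These 4 genes are the ones whose normalised counts in both libraries labelled overexpression are not multiples of the read step of their column. They are 4 of 22605 nonzero counts under the MCF-7 overexpression label and 4 of 22611 under the ZR-75 one. The TPM of all other genes left 323 TPM under the fixed total of a TPM column in the MCF-7 control and 302 in the ZR-75 control, and the deposited TPM of EIF4E, ESR1, FOXM1 and RUNX2 summed to 324 and 303. In the libraries labelled overexpression the remainder was 229 TPM under the MCF-7 label and 242 under the ZR-75 label, and the deposited TPM of the 4 genes summed to 12325 and 14239. The remainder was thus below that of the control under each set of labels. For EIF4E the deposited TPM gave ratios to control of 129.8 for MCF-7 and 138 for ZR-75, where the largest ratios the remainder allows are 2.68 and 2.58. Each largest ratio gives the whole remainder to a single gene and none to the others, so these ratios cannot hold together. A deposited ratio below its largest allowed value therefore does not show that the deposited value is right. For FOXM1 the deposited ratios were 10.03 and 11.3, and the largest allowed 2.08 and 2.44. ESR1 had a TPM ratio of 1.11 under the MCF-7 labels, where 1.81 is allowed, and 108 against 119 TPM under the ZR-75 labels, where a ratio of 2.25 is allowed, and its reads per TPM were 79.4 in both controls, 101 in the library labelled MCF-7 overexpression and 139.9 in that labelled ZR-75 overexpression. No level or change of these 4 genes is used in the comparisons that follow, except in alternatives that say so.

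**Figure D1:**
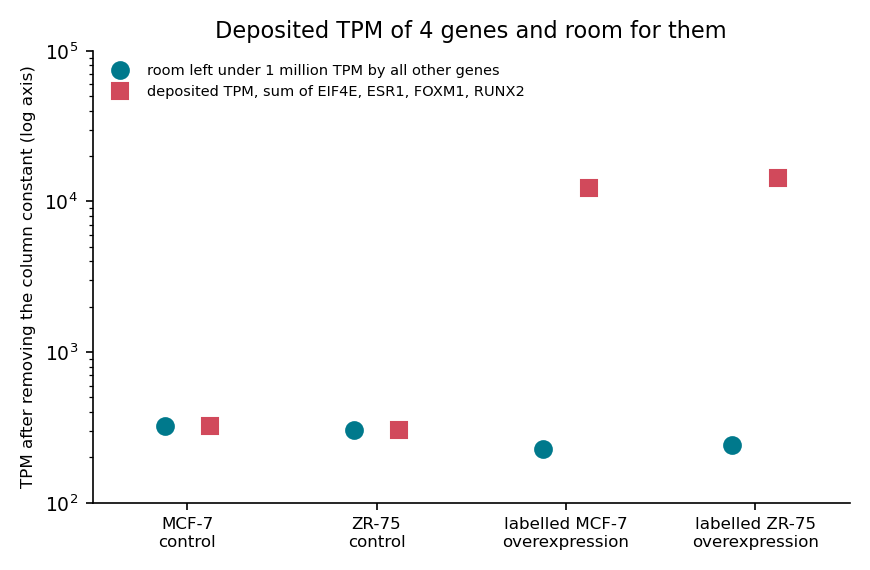
TPM (log axis) of EIF4E, ESR1, FOXM1 and RUNX2 together in each library: squares show the deposited sum and circles the amount that all other genes leave under the fixed total. In the controls the pairs coincide (324 and 323, 303 and 302), and in the libraries labelled overexpression the squares stand at 12325 and 14239 over circles at 229 and 242.

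Under the MCF-7 labels, the comparison was meant to ask how the mRNA profile differs with eIF4E overexpression. However, MTAP, which is deleted from the MCF-7 genome, stood at 100.4 CPM in the library labelled overexpression. The differences under both sets of labels are therefore not read as effects of eIF4E, since they may lie between cell lines. Epithelial and estrogen-regulated genes were far lower in the library labelled overexpression. KRT19, a keratin of simple epithelia, went from 2532 CPM to 0 reads, at least 17381-fold lower, and TFF1, a secreted peptide induced by estrogen, from 708 CPM to 0 reads, at least 4863-fold lower. AGR2, a disulfide isomerase of the luminal secretory pathway, was at least 4691-fold lower, and the long noncoding RNA DSCAM-AS1 at least 6254-fold lower. IRS4, a docking protein of insulin and growth factor receptors, rested on 2 reads in the control and 24101 in the library labelled overexpression, a ratio of 10808 with a 95% interval of 11.55 to 16.45 on the log2 scale. VIM, the intermediate filament protein of mesenchymal cells, went from 0.433 to 754 CPM, a 1740.5-fold ratio (interval 9.79 to 11.98 on the log2 scale).

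The other large decreases under the MCF-7 labels were SPTSSB, a subunit of serine palmitoyltransferase, which was 4399.7-fold lower, the melanosome linker MLPH at least 3255-fold, the matrix glycoprotein THBS1 at least 2769.5-fold and the morphogen SHH at least 2597-fold lower. Among the increases, GSTP1, a glutathione transferase, MSN, which links membrane and actin, and PSAT1, an enzyme of serine synthesis, had 0 control reads and were at least 1526-fold, 1249.7-fold and 1012-fold higher. LDHB, a subunit of lactate dehydrogenase, stood at 1049 against 2.92 CPM, and CDKN2A, the locus of p16 and p14ARF, at 215 against 0.217 CPM. RP6-24A23.7 went from 0 reads to 24506, at least 7327-fold higher; it lies on the X chromosome from 108719949 to 108724944, beside IRS4 (108732482 to 108736409) and on its strand, so how reads were split between the pair is uncertain. In all, 7001 of 15603 genes differed at least 2-fold, 3617 higher and 3384 lower in the library labelled overexpression. The split depends on scaling, with 4328 higher and 2825 lower under library totals and 4149 and 2914 from TPM. There is no replicate check within the line.

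Under the ZR-75 labels, most of the same genes led. KRT19 went from 2398 CPM to 0 reads, at least 16670-fold lower, DSCAM-AS1 was at least 6233-fold and AGR2 at least 4097-fold lower. TFF1 kept 1 read of 15278, a 17435-fold lower ratio with an interval of -19.39 to -11.61 on the log2 scale. IRS4 went from 0 to 31688 reads, at least 9256-fold higher, and RP6-24A23.7 from 0 to 25968, at least 7585-fold higher. VIM stood at 721.5 against 1.15 CPM and LDHB at 962 against 2.24 CPM.

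GSTP1 and MSN each had 1 control read in ZR-75, with ratios of 4048 (interval 9.50 to 17.29 on the log2 scale) and 3804 (9.41 to 17.20), and CDKN2A had 2 (ratio 1748, 8.92 to 13.82). NID1, a basement membrane glycoprotein, was at least 981-fold higher. SPTSSB was 1939.8-fold lower, MLPH at least 3185-fold, THBS1 at least 2404-fold and the keratin KRT80 at least 2620.5-fold lower. In all, 7007 of 15787 genes differed at least 2-fold, 3402 higher and 3605 lower in the library labelled overexpression. The larger side turned with scaling, with 4079 higher and 3054 lower under library totals and 4142 and 3052 from TPM. Here too no replicate check is possible.

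Taking both lines, the changes ran in the same direction for nearly all genes that moved. KRT8 and KRT18, the paired keratins of simple epithelia, changed by -8.72 and -6.88 on the log2 scale (SE 0.0454 and 0.0558; adjusted p = 1.7e-08 and 4.3e-08, limma, lower in both lines), and KRT19 fell by 11.27 (SE 0.0702, adjusted p = 2.5e-08). GREB1, a cofactor of the estrogen receptor, fell by 5.59 (SE 0.0472), from 1592 and 1529 CPM in the controls to 31.95 and 30.8 CPM. CCND1, which drives entry into S phase, fell by 5.57, GATA3, a luminal transcription factor, fell by 6.59, and GFRA1, a receptor of the GDNF family, fell by 8.82. LDHB rose by 8.14 (SE 0.0708, adjusted p = 4.3e-08), and IRS4 by 10.31 (SE 0.131, adjusted p = 1.1e-07), on a scale of log2(CPM + 1) that understates the change of genes near 0.

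The remaining genes with the smallest p included, among those that fell, DSCAM-AS1 (log2 change -9.82), the oxidoreductase NQO1 (-6.90) and the actin-sequestering TMSB4X (-6.31). Among those that rose were RP6-24A23.7 (10.25), IGF2BP1, an mRNA-binding protein of fetal tissues (7.71), the kinase anchor AKAP12 (5.58), MSN (7.65), CDKN2A (7.46), GSTP1 (7.84), the aldose reductase AKR1B1 (7.22) and the protease ADAMTS1 (7.17). Adjusted p lay between 1.7e-08 for KRT8 and 1.8e-07 for ADAMTS1. KRT8 (chromosome 12, 52897187 to 52949954) and KRT18 (52948871 to 52952901) overlap on opposite strands, DSCAM-AS1 is antisense to DSCAM, and KRT8, KRT18 and TMSB4X have processed pseudogenes; the strand used for counting is not given in the sources used here, so their split between copies and strands is uncertain.

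Across the table, 12540 of 15345 genes passed the threshold (81.7%), 6343 higher and 6197 lower, of which 6306 changed at least 2-fold (3182 higher, 3124 lower) and 3199 less than 1.5-fold. With the ZR-75 labels exchanged 0 genes passed (0 at an unadjusted p under 0.05 with limma-trend, 1 with limma-voom), but that fit decides nothing. The shared change enters its residual, and its SE was, for example, 4.66 for RP6-24A23.7 and 1.44 for DDX60. By the rule of size, 3079 genes were higher and 3045 lower in both lines, of 15322 measured in both, where independent lists would share 764 and 727, and 8 genes moved in opposite directions; under library totals 3698 were higher and 2559 lower in both. The log2 changes of the lines correlated across genes with r = 0.979 and a Spearman rho of 0.970; genes are not independent replicates. Libraries under the same state label were alike. Between the controls 456 genes (3.16%) differed at least 2-fold, 436 of them higher and 20 lower in ZR-75. Between the libraries labelled overexpression 53 genes (0.368%) did, 25 higher and 28 lower. The comparisons under both sets of labels are therefore close to a single comparison repeated. Their overlap, correlation and count of genes that passed follow largely from that likeness and are not read as replication in separate lines.

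**Figure D2:**
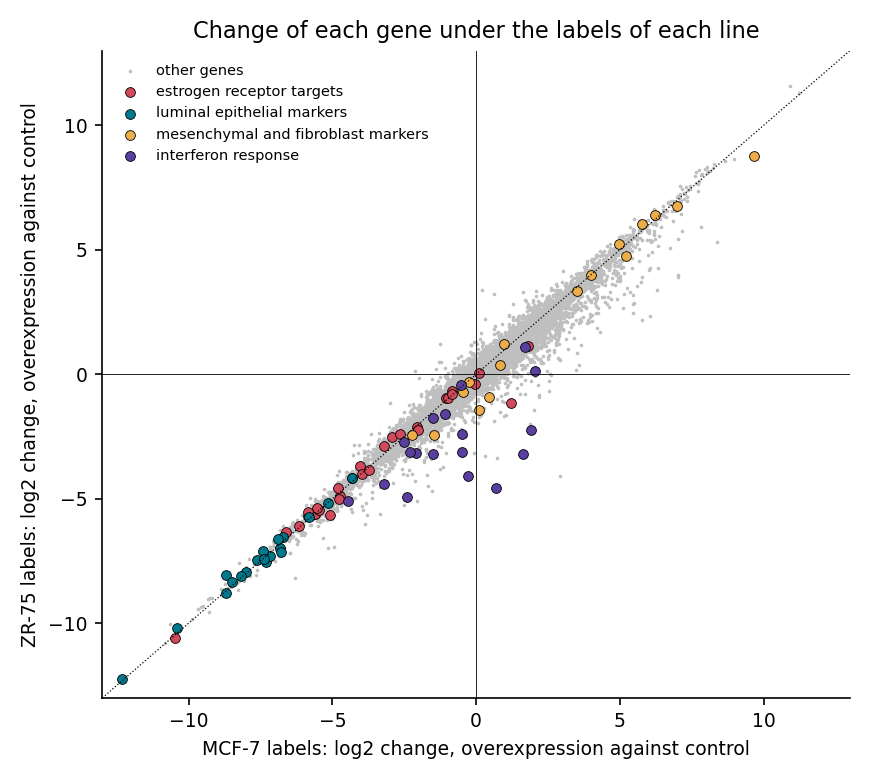
Log2 change of each gene, library labelled overexpression against control, under the MCF-7 labels (x axis) and the ZR-75 labels (y axis), with members of 4 gene lists coloured and a dotted line of equality. Points follow the line (r = 0.979), luminal markers lie at the lower left, and interferon response genes lie below the line (medians -0.82 for MCF-7 and -3.12 for ZR-75).

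Luminal and estrogen-regulated groups were lower together. All 19 measured luminal epithelial markers fell, 0 rose and 0 did not pass (camera adjusted p = 2.7e-09; adjusted p = 0.874 with an estimated correlation), with a median log2 change of -7.38 under the MCF-7 labels and -7.43 under the ZR-75 labels, at percentile 0 of random lists in each. AGR2 fell by 9.31, and SPDEF, an epithelial transcription factor, fell by 7.54. Of 30 estrogen receptor targets 26 fell, 1 rose and 3 did not pass (camera adjusted p = 6.5e-08; adjusted p = 0.874 with an estimated correlation), with medians of -3.99 and -3.91. Among them TFF1 fell by 9.56, the progesterone receptor gene PGR fell by 6.11, IGFBP4, which binds insulin-like growth factors, fell by 6.01, and the chemokine CXCL12 fell by 5.60. Of 10 basal epithelial markers 8 fell, 1 rose and 1 did not pass (camera adjusted p = 0.00955; adjusted p = 0.874 with an estimated correlation), among them the integrin ITGB4 (-7.08), SFN (-6.04), the cadherin CDH3 (-5.75) and the laminin chain LAMB3 (-4.36). Their medians were -3.61 and -3.60. With members at 0 reads set to their bound, the luminal medians became -8.02 and -7.47, the basal -4.82 and -4.86, and the estrogen receptor target median under the MCF-7 labels -4.18. In the same way the mesenchymal and fibroblast medians became 2.98 in each line, and the NF-kB median under the ZR-75 labels went from -2.17 to -3.05.

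Of 16 mesenchymal and fibroblast markers 10 rose, 4 fell and 2 did not pass, and the list did not pass (camera adjusted p = 0.0718; adjusted p = 0.969 with an estimated correlation); its medians were 2.25 and 2.29, at percentiles 99.99 and 100. VIM rose by 8.72, SNAI2, a repressor of epithelial genes, by 6.07, the neural cadherin CDH2 by 5.35 and ZEB2 by 4.93. Moving with these groups, the gene MTAP went from 0.381 and 0.9996 CPM in the MCF-7 and ZR-75 controls to 100.4 and 108 CPM, and CD44, a hyaluronan receptor, from 182 and 187 CPM to 0 reads. The neuronal filament genes NEFL, NEFM and INA and the let-7 regulator LIN28B, at or under 1 read in the controls, stood at 33.6, 37.5, 48.3 and 108 CPM under the MCF-7 overexpression label and at 33.6, 36.2, 47.2 and 123 CPM under the ZR-75 one. These markers of cell lines were chosen after part of the data had been seen. Of the immune cell markers, only 3 were measured: CD19 rose by 1.44, ITGAM fell by 0.98, and CD68 had -0.35 (SE 0.457, adjusted p = 0.502); the list did not pass (camera adjusted p = 0.965).

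**Figure D3:**
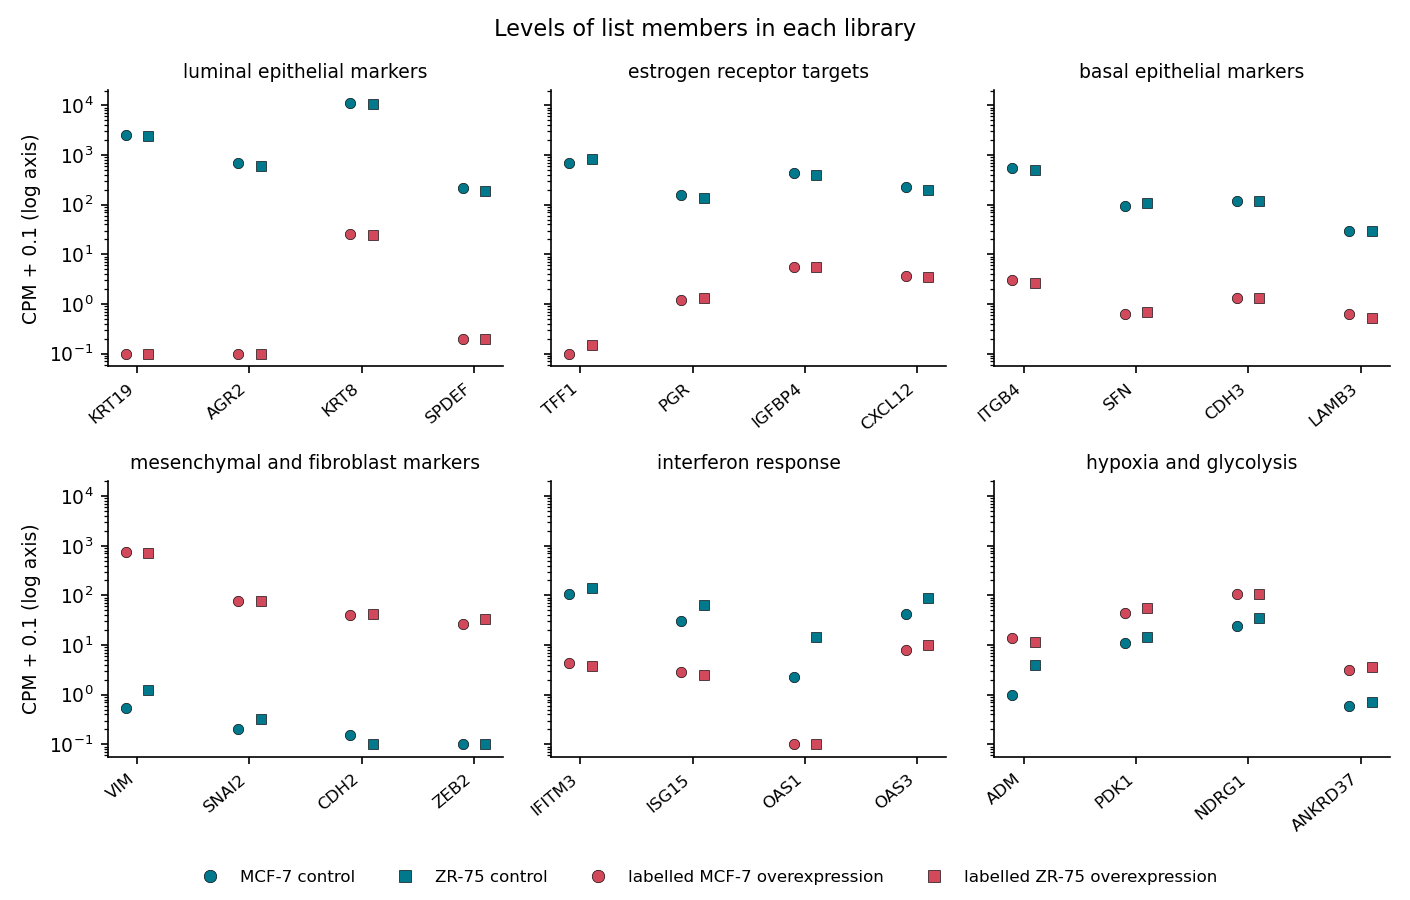
CPM + 0.1 (log axis) of the 4 most changed members of 6 gene lists in each library; circles are MCF-7 and squares ZR-75 labels, blue the controls and red the libraries labelled overexpression. KRT8 stood at 11202 and 10805 CPM in the controls against 26.2 and 24.2 CPM, and VIM at 0.433 and 1.15 CPM against 754 and 721.5 CPM.

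For the translation and cell cycle groups, which the series title points to, members went both ways and no list passed with camera. Of 39 translation initiation factors other than EIF4E, 22 rose, 11 fell and 6 did not pass, and the list did not pass (camera adjusted p = 0.218), with medians of 0.42 and 0.32 at percentiles 99.9 and 99.7. EIF5B, which joins the ribosomal subunits, rose by 1.70, and the EIF3 subunits EIF3A and EIF3I rose by 1.32 and 1.14; EIF3D rose from 127 and 129.9 CPM to 284.5 and 269.5 CPM. Of 78 cytosolic ribosomal proteins 36 rose, 29 fell and 13 did not pass (camera adjusted p = 0.658), from RPL5 (1.37) and RPLP2 (1.29) to RPL30 (-1.14) and RPS21 (-1.35). Of 15 mRNAs listed as eIF4E-sensitive 5 rose, 7 fell and 3 did not pass (camera adjusted p = 0.576). CCND1 (-5.57), the kinase gene PIM1 (-1.96) and the survival gene BCL2L1 (-1.49) fell, and the growth factor gene FGF2 rose by 4.22. These are mRNA levels, and translation was not measured, so they do not test eIF4E activity. Of 27 FOXM1 and G2/M genes other than FOXM1, 10 rose, 15 fell and 2 did not pass (camera adjusted p = 0.550). The kinetochore genes CENPF and CENPE rose by 2.84 and 2.28, while the mitotic kinase gene AURKA (-1.72) and the phosphatase gene CDC25B (-1.26) fell. Of 26 G1/S and DNA replication genes 17 rose, 6 fell and 3 did not pass (camera adjusted p = 0.105), led by the histone chaperone subunit CHAF1A, which rose from 56.2 and 53.4 CPM to 161 and 153.0 CPM, and the replication licensing factor CDC6 (1.23), with MCM10 (0.90) and the folate enzyme DHFR (0.89).

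Genes of tamoxifen metabolism and drug transport were mostly lower: of 12, 8 fell, 1 rose and 3 did not pass (camera adjusted p = 0.0417; adjusted p = 0.969 with an estimated correlation). The hydroxysteroid dehydrogenase AKR1C2 (-7.58), the estrogen hydroxylase CYP1B1 (-6.97), the efflux pump ABCC3 (-5.61) and the glucuronosyltransferase UGT2B15 (-4.38) fell. Hypoxia and glycolysis genes were mostly higher, with 16 of 21 that rose, 3 that fell and 2 that did not pass (camera adjusted p = 0.0343; adjusted p = 0.874 with an estimated correlation). The vasodilator peptide ADM rose by 2.17, the pyruvate dehydrogenase kinase PDK1 by 1.87, NDRG1 by 1.86 and ANKRD37 by 1.48. Of 11 NF-kB and cytokine genes all 11 fell (camera adjusted p = 0.000972; adjusted p = 0.874 with an estimated correlation), among them TNFAIP2 (-4.79), the adhesion molecule ICAM1 (-4.42), the NF-kB inhibitor NFKBIA (-3.69) and BIRC3 (-2.47). Of 18 interferon response genes 13 fell, 2 rose and 3 did not pass (camera adjusted p = 0.0374; adjusted p = 0.969 with an estimated correlation). Here the antiviral membrane protein IFITM3 (-4.64), the ubiquitin-like ISG15 (-3.62) and the oligoadenylate synthetases OAS1 (-2.81) and OAS3 (-2.65) fell.

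Of the 23 lists, 8 passed with camera's preset correlation, 1 higher and 7 lower, and fry called 5. With an estimated correlation 0 passed, but that test has 1 degree of freedom, so it decides nothing. For luminal markers the estimated correlation was -0.029, yet the unadjusted camera p went from 1.2e-10 to 0.090. The upper ends of the ranges that follow come from that test. Over the alternatives, adjusted p ran from 0.00837 to 0.874 for basal markers, 0.00087 to 0.874 for NF-kB genes, 0.00787 to 0.874 for histones, 0.0326 to 0.969 for interferon response, 0.0320 to 0.874 for hypoxia and glycolysis, 0.0377 to 0.969 for tamoxifen metabolism, and 0.0569 to 0.969 for mesenchymal markers. For the response to the overexpression label, counts of members adjusted over the list alone equalled those over all genes for each list except the histones, where 11 rather than 10 fell. With library totals alone the median changed sign for eIF4E-sensitive mRNAs under the MCF-7 labels and for FOXM1 and G2/M genes under the ZR-75 labels.

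**Figure D4:**
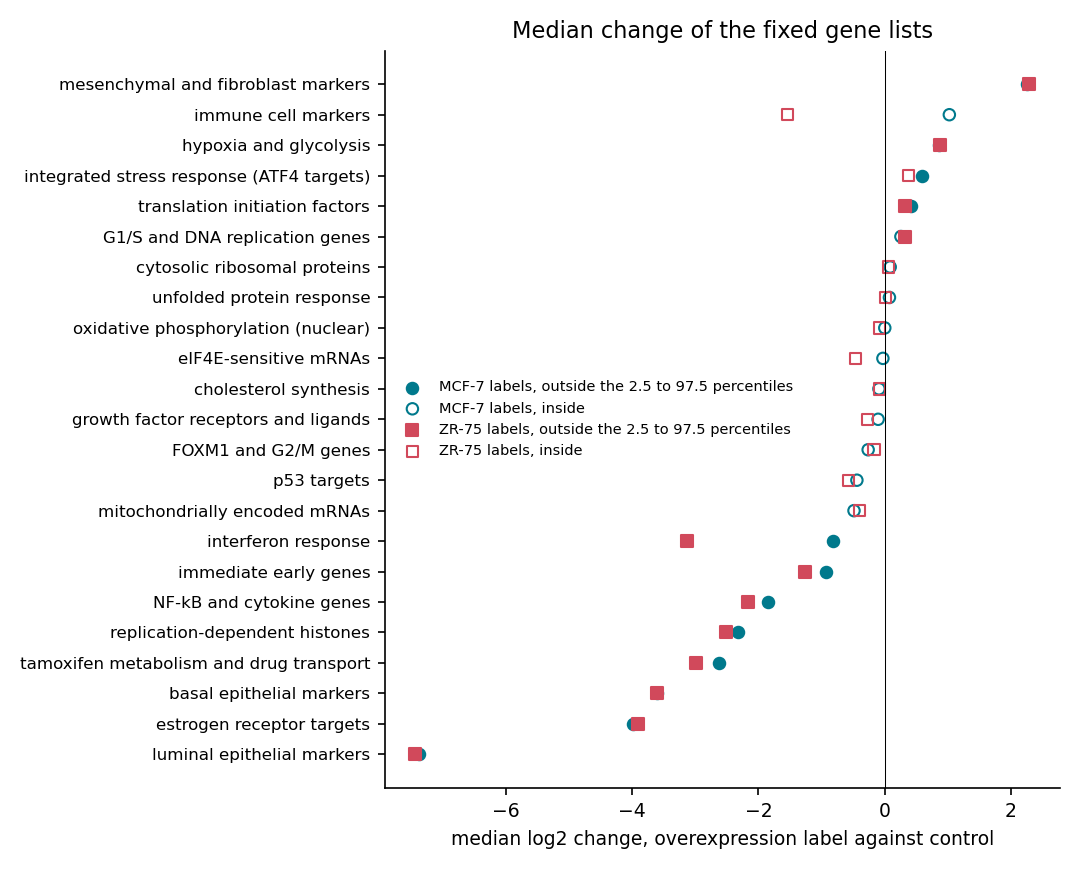
Median log2 change of each of the 23 gene lists (x axis), library labelled overexpression against control; circles are MCF-7 and squares ZR-75 labels, filled where the median lies outside the central 95% of 10000 matched random lists. In each line 12 medians lie outside, from luminal markers (-7.38 and -7.43) to mesenchymal and fibroblast markers (2.25 and 2.29).

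Between the lines, interferon response genes differed most among the lists in the controls, and little in the libraries labelled overexpression. Their median was 1.18 higher on the log2 scale in the ZR-75 control than in the MCF-7 control, at percentile 100 of random lists, and 11 of 18 were at least 2-fold higher; between the libraries labelled overexpression it was 0.06, and 0 of 18 were. DDX60, a helicase induced by interferon, stood at 0.0541 CPM in the MCF-7 control and 63.9 CPM in the ZR-75 control, IFI27 at 0.812 and 56.8, IFI44L at 0 and 15.05, and IFIT1 at 0.704 and 22.7 CPM. LRP2, an endocytic receptor, stood at 5.52 and 99.7 CPM. In the libraries labelled overexpression DDX60 was at 3.69 and 3.31 CPM and LRP2 at 21.5 and 24.8 CPM.

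Other lists differed by less. In the controls the ZR-75 to MCF-7 medians of immediate early genes (0.35), ATF4 targets (0.19) and hypoxia and glycolysis genes (0.16) lay at percentile 100, those of p53 targets (0.13) at 99.6 and of tamoxifen metabolism genes (0.30) at 99.1. FOXM1 and G2/M genes (-0.17), G1/S genes (-0.14) and mitochondrially encoded mRNAs (-0.16) lay at percentile 0, and cholesterol synthesis genes (-0.10) at 0.32. Between the libraries labelled overexpression, cytosolic ribosomal proteins (-0.13) lay at percentile 0 and nuclear oxidative phosphorylation genes (-0.10) at 0.01. In the line term of the model over all 4 libraries, camera with its preset correlation passed 8 of 23 lists, 2 higher and 6 lower in ZR-75. With an estimated correlation 0 passed, again from 1 degree of freedom, so that count decides nothing. Interferon response genes were higher (camera adjusted p = 1.1e-05; adjusted p = 0.784 with an estimated correlation), as were hypoxia and glycolysis genes (camera adjusted p = 0.0187; adjusted p = 0.784 with an estimated correlation). Ribosomal proteins (camera adjusted p = 3.1e-10), G1/S genes (0.000740), mitochondrially encoded mRNAs (0.00122), oxidative phosphorylation genes (0.00327) and translation initiation factors (0.0356) were lower, each with adjusted p = 0.784 with an estimated correlation. The median line coefficients were small: -0.095 for ribosomal proteins, -0.064 for oxidative phosphorylation genes and -0.049 for initiation factors. In the controls these lay at percentiles 64.9, 45.0 and 51.7 of random lists. There they were not lower than genes of like expression, on which camera does not match. FOXM1 and G2/M genes were lower too (camera adjusted p = 0.00169; adjusted p = 0.792 with an estimated correlation). No member of any list passed for the line over all genes; adjusted over the list alone, 2 mitochondrially encoded mRNAs were lower in ZR-75 and no member of another list passed.

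Genes that mark breast cancer subtypes differed little between the controls labelled MCF-7 and ZR-75. PGR stood at 159.5 CPM in the MCF-7 control and 137 CPM in the ZR-75 control, GATA3 at 1592 and 1433, FOXA1 at 469 and 434, the epithelial cadherin CDH1 at 1549 and 1384, the receptor ERBB2 at 86.8 and 97.4, and TP53 at 257 and 250.3 CPM. The lowest ZR-75 to MCF-7 coefficients over both states were those of RP11-717F1.2 (-0.60), CITED4 (-0.60), RP11-212P7.2 (-0.50), TMEM189-UBE2V1 (-0.48) and RP11-386G11.10 (-0.43), with adjusted p from 0.792 to 0.795. The highest were those of DDX60 (2.91), IFI27 (2.58), LRP2 (2.07), IFI44L (2.05) and IFIT1 (1.96), each with an adjusted p of 0.792. In the model over all 4 libraries 0 genes passed for the line (limma-trend; 837 at an unadjusted p under 0.05; 0 and 697 with limma-voom; 1 with median-ratio scaling). A difference held only by the controls enters the residual of this fit as much as the line coefficient. The count of 0 therefore does not show that the controls are alike. DDX60, at 0.0541 and 63.9 CPM in the MCF-7 and ZR-75 controls, had a line coefficient of 2.91 with an SE of 1.24. Line and culture medium cannot be told apart in this comparison.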

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

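None of the tests in this part was chosen only after the result was seen, and the opposite directions it lists were looked for by a rule set before the data were examined. In each case the library labelled overexpression lay above its control in MCF-7 and below it in ZR-75, with 1 library per group. The limma fit with the ZR-75 labels exchanged passed none of the 5 genes (adjusted p = 1 for each of DDX60, IFI44L, IFIT1, LRP2 and CD68), but its residual holds the change the lines share, so it had little power and leaves the differences open. For DDX60 the log2 change was 2.92 in MCF-7 and -4.08 in ZR-75, a difference of -7.00. For IFI44L it was 1.65 and -3.19, a difference of -4.84, and for IFIT1 1.91 and -2.23, a difference of -4.14. These 3 genes are induced by interferon, and the libraries labelled overexpression held 3.69 and 3.31 CPM of DDX60, so the opposite directions arise from the controls, at 0.0541 and 63.9 CPM. LRP2 changed by 1.87 and -1.99, a difference of -3.86. CD68, a lysosomal protein of macrophages, changed by 1.03 and -1.64, a difference of -2.67, and with it the median of the 3 measured immune cell markers, at 1.03 and -1.54, differed by -2.57.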

How the results depend on the processing

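The alternatives chosen only after the data were seen were test pseudocounts of 0.5 and 2 CPM, keeping the 4 genes off the read grid, and the highest EIF4E level that the TPM total allows; all others, like the gene lists, were chosen before the data were examined. Of 61 alternative values of the main results 47 stayed within their limits and 14 moved. The shared response held between 10393 and 13182 genes, and 12531 with the 4 genes kept. With a 4-fold threshold, which by construction counts fewer genes, 3142 genes differed in MCF-7, 3131 in ZR-75 and 2706 the same way in both. The correlation between lines was 0.986 with genes of at least 5 CPM, 0.989 at 10 CPM and 0.970 as Spearman's rho; the cause was not tested. The EIF4E log2 change was 7.18 in MCF-7 and 7.38 in ZR-75 with library totals, 7.10 in ZR-75 from TPM, and at most 1.42 and 1.37 where EIF4E is held to the TPM total, which by construction removes the excess. Median-ratio scaling gave 1 gene that differed between lines, where 0 passed otherwise; the cause was not tested. Of the 23 lists 0 passed with estimated correlations, which come from 1 residual degree of freedom, and 5 with fry, which asks whether a list's own genes move: luminal and basal markers, histones and estrogen receptor targets lower, translation initiation factors higher (adjusted p = 0.0493, from 0.0493 to 0.874 over the alternatives). Adjusted p over the alternatives ran from 2.1e-09 to 0.874 for luminal markers and from 5.9e-08 to 0.874 for estrogen receptor targets. The immune cell marker list turned direction with fry (adjusted p = 0.474, from 0.474 to 0.984 over the alternatives), without passing either way. Of 834 alternative values of single genes 399 stayed within the counting interval, 435 moved and 0 named genes that were called changed direction. The labels alone pair the libraries by cell line, which serves as the block of the fit, and without it 12442 genes passed. A DESeq2 Wald test and the legacy quasi-likelihood were not run, since the values are not raw counts, and leaving out a line leaves no residual degree of freedom. Depth limits genes under about 0.156 CPM, and the lack of replicate cultures limits every comparison.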

Other observations

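Tests chosen only after the result was seen were the 3 on the deposited values of EIF4E, ESR1, FOXM1 and RUNX2, the chi-square between the controls, and the use of the interval of the MTAP ratio in ZR-75 to decide; the predictions on MTAP and on cell line markers were written before those genes were looked up, with CD44, CDKN2A and IRS4 already seen. The upper limits given for MTAP in the controls were not part of those predictions. Several gene lists have not yet been described. Replication-dependent histones, as measured in polyadenylated RNA only, were lower, which need not hold for all histone mRNA. Of 13, 10 fell, 1 rose and 2 did not pass (camera adjusted p = 0.00839, and adjusted p = 0.874 with an estimated correlation). Those that fell included HIST2H2BE (-4.59), HIST1H2AC (-3.23), HIST1H4H (-3.02) and HIST1H2BD (-2.84). Of 20 p53 targets 12 fell, 4 rose and 4 did not pass (camera adjusted p = 0.0814), led by the stress cytokine GDF15 (-6.59), with PHLDA3 (-3.92), the cell cycle inhibitor CDKN1A (-3.30) and TP53INP1 (-2.58). Of 20 immediate early genes 11 fell and 9 rose (camera adjusted p = 0.277); PHLDA1 (-5.42), the phosphatase gene DUSP4 (-5.34), FOSL2 (-4.38) and EGR3 (-4.28) fell. Of 19 growth factor receptors and ligands 10 fell, 8 rose and 1 did not pass (camera adjusted p = 0.550): the receptor ERBB3 (-5.76), IGFBP5 (-5.11) and the ligand AREG (-4.52) fell, and FGF2 rose by 4.22. The median of this list changed sign under the MCF-7 labels with library totals alone.

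Among metabolic and stress genes, 13 of 20 ATF4 targets of the integrated stress response rose and 7 fell (camera adjusted p = 0.448); the serine synthesis genes PSAT1 and PHGDH rose by 6.26 and 2.81, and CEBPB (-2.25) and VLDLR (-2.16) fell. Of 20 unfolded protein response genes 9 rose, 8 fell and 3 did not pass (camera adjusted p = 0.927), from XBP1 (-4.24), DNAJB11 (-0.96) and SEL1L (-0.79) to HERPUD1 (0.72). Of 21 cholesterol synthesis genes 6 rose, 9 fell and 6 did not pass (camera adjusted p = 0.782); STARD4 and SC5D rose by 2.87 and 1.30, and the receptor LDLR (-1.23) and the reductase DHCR7 (-1.16) fell. For these last 2 lists and for the immune cell markers the median, the mean and the test did not all have 1 sign. Of 29 nuclear oxidative phosphorylation genes 10 rose, 12 fell and 7 did not pass (camera adjusted p = 0.758), with COX6C (-2.94), NDUFB5 (-1.05) and COX4I1 (-1.04) lower and NDUFB8 (1.34) higher; the median of this list and that of cholesterol synthesis changed sign with scaling. Of 13 mitochondrially encoded mRNAs 9 fell, 0 rose and 4 did not pass (camera adjusted p = 0.0602), among them MT-ND5 (-1.10), MT-CO2 (-1.05), MT-CYB (-0.79) and MT-ND4 (-0.51).

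The deposited EIF4E, ESR1, FOXM1 and RUNX2 values stand apart in both libraries labelled overexpression. Rounding was argued against, since only 4 of 22605 nonzero counts under the MCF-7 overexpression label were off the read grid, and 4 of 22611 under the ZR-75 one. The prediction counted other genes with at least 1000 estimated reads off the grid. That count of 0 follows from how the 4 genes were picked, so it is no test. Transgene reads counted in the same quantification were argued against too, because the deposited EIF4E TPM exceeded the remainder left by all other genes by at least 10852 TPM, and a transgene would have lowered the TPM of the rest. A candidate explanation is that these 4 values were taken from another step than the rest of their columns. It met a prediction that was written only after the values had been seen, so this is a description more than a test. Their sum exceeded the remainder by at least 12097 TPM in the libraries labelled overexpression and by at most 0.83 TPM in the controls. Which step that was stays open, and no biological explanation was tested for the grid.

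Between the libraries labelled overexpression and their controls, 7001 genes in MCF-7 and 7007 in ZR-75 differed at least 2-fold. Overexpression in MCF-7 cells was argued against by MTAP, which is deleted from the MCF-7 genome: 0.381 CPM in the control (upper 95% limit 0.783) and 100.4 CPM in the library labelled MCF-7 overexpression, while scaling moved the count of 2-fold genes by at most 1.02 times. A mesenchymal breast cancer line was argued against by 0 of 6 markers at 10 CPM or more in both libraries, CAV1 being highest at 9.37 and 9.30 CPM. A candidate explanation that met its prediction is RNA of an embryonic kidney (HEK293) type of line under both overexpression labels: 4 of 5 markers (NEFL, NEFM, INA and LIN28B, at 33.6 to 123 CPM) passed in both and under 1 CPM in both controls, PAX2 reached 2.77 and 1.58 CPM, and IRS4, seen beforehand, was at 1170.2 and 1519 CPM. Overexpression in the ZR-75 cells of the control was argued against by MTAP less firmly, since no deletion in that line is known here and strong regulation was not tested: predicted to differ by less than 2-fold, it went from 0.9996 CPM (upper limit 1.58) to 108 CPM, a ratio of 108 with an interval of 6.12 to 7.54 on the log2 scale.

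The control libraries labelled MCF-7 and ZR-75 were alike, with 3.16% of genes 2-fold apart, though 436 of these 456 genes were higher in ZR-75. A single library deposited under both labels was argued against, since the median chi-square between them was 1.61, above sampling noise, and 11 of 18 interferon response genes were at least 2-fold higher in ZR-75. Cells of 1 line under both labels, with a difference in culture, met the prediction written beforehand (CDKN2A already seen) at the point values. MTAP and CDKN2A, deleted from MCF-7, reached at most 0.9996 CPM in either control, under the 1 CPM predicted for 1 line. The 10 CPM or more predicted in ZR-75 for separate lines was not met. The upper limit of 1.58 for MTAP in ZR-75 passes 1 CPM, though limits were not part of the prediction. No value known here for ZR-75 cells decides, so 1 line and separate lines cannot be told apart. A difference between the lines or their media, named by the design, remains untested.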
